A study of Caenorhabditis elegans with 2 samples.

How the data were processed

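Peak lists were taken as the authors deposited them, for 2 biological replicates of CEH-16 immunoprecipitation in L3 larvae, 1 group in all; the group and replicate numbers come from the labels. Per the labels, chromatin was fragmented by sonication and reads were placed on ce10 and ce11. Per the provenance text deposited with the samples, the lists were made against a control, which was not analysed here. The aligner and the peak caller were not given in the sources used here. The authors called peaks for each replicate and on pooled replicates, and the thresholded list is the one they passed by the irreproducible discovery rate (IDR).

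Each deposited list gives a signal per peak, the authors' own value, whose scale is not stated, and a score in the q column, which is below 0 for most peaks of the deposited pooled and replicate 2 lists and so was not read as a probability. Both values were used to rank or describe peaks within a list. The signal was also correlated between matched replicate peaks, and the IDR model compared their ranks by signal or, in a variant, by the score. The pooled and replicate 2 lists both stop at exactly 30000 peaks and the replicate 1 list does not, so ranks were not compared between lists as a change. One interval is listed 2 times with different summits and both entries were kept. The lists give no read counts, so depth per replicate is unknown, and intervals on shares cover counting of peaks only.

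All coordinates are on ce11 and 1-based. No peak ran past the end of a chromosome of the reference. Genes came from Ensembl release 115. Each summit was assigned to the nearest start of a protein-coding or miRNA gene. Summits were matched between lists within 200 bp, and correlations and the IDR model used mutually nearest pairs. Promoter proximity meant 1000 bp, motif windows 50 bp to each side with flanks 500 bp away, and tRNA proximity 200 bp. The background was the pooled peaks outside the thresholded list. Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family (7 chromosomes, 16 gene lists, all 6-base words), flanks by exact McNemar tests, the mean of both flanks by permuting the 3 windows of each summit (this replaced, after its result was seen, a McNemar test that counted each summit 2 times), and replicate overlap by 1000 circular shifts within chromosomes, one-sided; other overlap settings used 50 to 200 shifts. Intervals are exact Clopper-Pearson at 95%.

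The IDR model, a Gaussian copula mixture fitted by expectation maximisation, was changed after its first run. From the single starting point used at first, the mixing share went to its upper limit and all 5480 matched peaks passed, which is no usable count. The fit now runs from 24 fixed starting points and keeps the highest copula likelihood, without regard to the number of peaks. The first check on simulated data had used a different starting value from the real run and so missed the failure. It now calls the same routine, and recovered 88.3% of 300 planted peaks among 5000, with 6.36% false among those called. The planted peaks were a smaller share and stood further from the rest than in the fit to the data (share 15.0%, mean 1.18). These rates therefore do not measure recovery in the data. On simulated data the 6-base scan recovered its planted word among 5 called, the list test its planted list with 1 of 16 called, and the overlap step 97.3% of planted shared sites.

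The gene lists were fixed before the data were examined: seam and epidermal regulators, cell fusion and apical junction, Wnt pathway, heterochronic, Hox and cofactors, cuticle collagen and moulting, hedgehog-related, homeobox, nuclear hormone receptors, neuropeptides, pan-neuronal, intestine, body-wall muscle, pharynx, germline and ribosomal proteins. Members were matched by gene symbol. The annotation names miRNA genes with a species prefix that the lists lack, so the miRNAs of the heterochronic list were not matched. Genes named were to be those of the 25 strongest thresholded peaks, list members assigned a thresholded peak (up to 4 per list by signal), and always ceh-16, eff-1, egl-18, elt-6, apr-1 and unc-119. Since 23 of the 25 strongest peaks were mitochondrial, these are described as a group and the strongest nuclear peaks are named beside them, a choice made after the values were seen, as are the extra ribosomal protein genes beyond 4. Alternatives covered windows, matching rules, thresholds, backgrounds, builds and each replicate alone; nuclear-only and autosomal-only versions and the single-start IDR fit were added after seeing the data. With each replicate left out, the 214 strongest peaks of the other took the place of the thresholded list. The remaining peaks of that same replicate then took the place of the pooled background. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.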

Results

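CEH-16, the worm homologue of the homeodomain protein engrailed, was mapped by chromatin immunoprecipitation and sequencing in L3 larvae of a transgenic strain that carries CEH-16 fused to GFP and FLAG at its C terminus. Whole animals of mixed sex were used, and 2 biological replicates form the only group, so no contrast between conditions exists. The list for replicate 1 held 19150 peaks and the list for replicate 2 held 30000, both called at a relaxed setting, and the list from the pooled replicates held 30000. The list thresholded by reproducibility (irreproducible discovery rate, IDR) held 214 peaks. The lists carry no read counts, so the depth behind each peak is unknown. Coordinates are on ce11.

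The mitochondrial genome held 25 of the 214 thresholded peaks, and these included the 22 of highest signal in the list. The strongest, with its summit at M 12452, had a pooled signal of 2989, against 1096 in replicate 1 and 1982 in replicate 2. The median pooled signal was 909 for the 25 mitochondrial peaks and 53.0 for the 189 nuclear peaks. Mitochondrial peaks made up 23 of the 25 strongest peaks, with summits in the coding sequences of ND1, ND6 and COX3 among others. Every mitochondrial peak of the pooled list was in the thresholded list, which was also exactly the 214 pooled peaks of highest signal. The signal is the authors' own value for each peak. It is used here to rank or describe peaks within a list and to relate matched peaks of the 2 replicates.

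**Figure D1:**
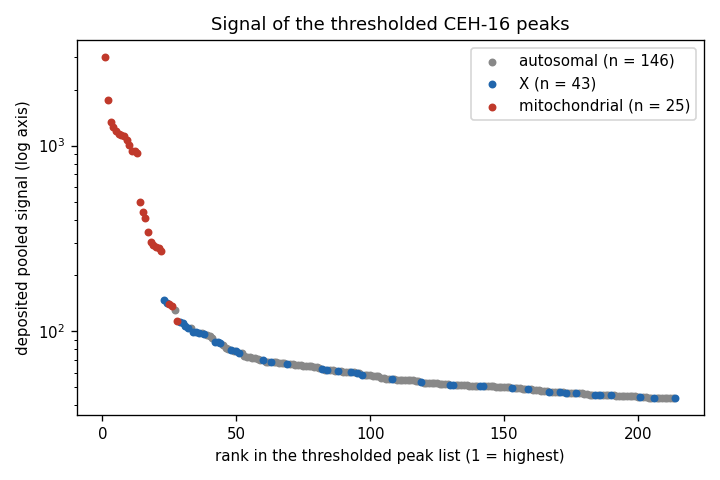
Deposited pooled signal (log axis) against rank for the 214 thresholded peaks, 1 point per peak, coloured by mitochondrial, X or autosomal position. Mitochondrial points reach 2989, and the highest nuclear point lies at 148.

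Among the nuclear peaks, the X chromosome supplied 15 of the 25 strongest, a set singled out after the values were seen because mitochondrial peaks filled most of the top of the list. The strongest lay on X from 11094026 to 11094375, outside protein-coding genes and with W02H3.3 as the nearest start, at a pooled signal of 148 (50.2 in replicate 1 and 99.2 in replicate 2). The next lay on X from 14525772 to 14526121, upstream of nspc-17, at 141. A peak on X from 6296374 to 6296723 lay in an intron of mom-1, which encodes a factor needed for Wnt secretion, at 111, and one on X from 5429326 to 5429675 lay in the coding sequence of pks-1 at 106. A peak at X 8036412, outside protein-coding genes, had xol-1, the switch gene of sex determination, as its nearest start at a pooled signal of 98.2. The autosomal peaks in the same set included those upstream of the ribosomal protein genes rpl-3 (III from 3867421 to 3867770, signal 131) and rpl-35 (III from 7854487 to 7854836, signal 104.1), and of cdc-48.1 (95.8), which encodes an AAA ATPase.

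Most of the strongest peaks of a replicate were present in the other's list, fewer of them near its top. Of the 200 strongest replicate 1 peaks, 85.5% had a replicate 2 summit within 200 bp (exact 95% interval 79.8 to 90.1), and the share was 23.4% for the 9150 peaks of lowest rank. Against only the top 1000 of replicate 2, the share of those 200 was 62.5%. Of the 214 strongest replicate 1 peaks, 91 lay within 200 bp of one of the 214 strongest of replicate 2 (69 of 189 nuclear peaks). Over the whole lists, 29.4% of replicate 1 peaks had a replicate 2 summit within 200 bp, against 11.8% by chance, and 18.9% of replicate 2 peaks had a replicate 1 summit, against 7.56%. Each share had a one-sided permutation p of 0.001 over 1000 circular shifts, the smallest these can give. Across the 5480 matched peaks, which are not independent replicates, Spearman's rho of the signal was 0.23 and Pearson's r of the log2 signal was 0.56 (0.22 and 0.39 for the 5458 nuclear matched peaks). Among the 188 nuclear thresholded peaks found in both lists, rho was 0.04, but these are selected on the pooled signal of both replicates, which by itself can lower such a correlation, so the value alone does not show disagreement. The 22 mitochondrial matched peaks gave 0.89. Both replicate lists held a summit within 200 bp for 210 of the 214 thresholded peaks, and 166 were in the top 1000 of both. The peak nearest to sma-9, a zinc-finger gene, at X 10766432 was in the replicate 2 list only.

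**Figure D2:**
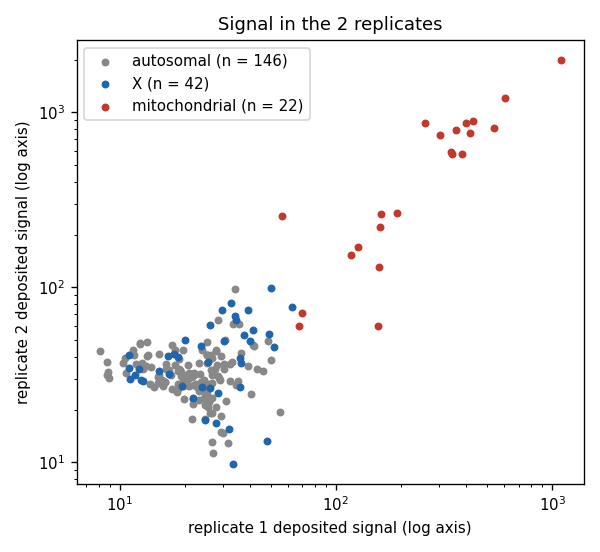
Deposited signal in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis) at the 210 thresholded peaks present in both replicate lists, 1 point per peak. The 22 mitochondrial points spread along the diagonal, and the nuclear points, selected on pooled signal, form a cloud.

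A reproducibility model fitted here to the matched replicate peaks placed 218 of the 5480 under an IDR of 0.05, of which 196 were nuclear and 164 lay within 200 bp of a thresholded peak. The fit was the one of highest likelihood among 24 starting points, a step brought in after the single starting point used at first had collapsed to 1 component and put all 5480 peaks under the threshold. From 20 of the 24 starts the fit reached the same likelihood to within 1 unit, and from 4 it collapsed. Under an IDR of 0.01 the count was 124.

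Thresholded peaks lay near gene starts more often than the other pooled peaks. A start of a protein-coding gene was within 1000 bp of 63.1% of the 214 summits (exact 95% interval 56.2 to 69.6) and of 38.6% of 29786 pooled summits outside the list (two-sided Fisher's exact test, odds ratio 2.71, p = 7.21e-13). For the 189 nuclear peaks alone the share was 58.7% (Fisher's exact test, odds ratio 2.26, p = 3.1e-08). The other pooled peaks held no mitochondrial peak, so mitochondrial summits raised the contrast for all 214 without a background of their own. By position, 129 of the nuclear summits were outside protein-coding genes, 43 in introns, 7 in coding sequence, 5 in 5' UTRs and 5 in 3' UTRs. Only protein-coding genes were used for these classes, so summits at tRNA or other small RNA genes can count as outside. The share in coding sequence was 3.70% against 17.1% for the other pooled peaks (Fisher's exact test, Benjamini-Hochberg adjusted p = 7.93e-08). Of 113 nuclear peaks within 1000 bp of their assigned start, 95 lay upstream, a share not compared with that of the other pooled peaks. On X, 15 of 43 thresholded peaks (34.9%) were within 1000 bp of a start, against 96 of 146 on the autosomes (65.8%), a comparison chosen after seeing the data (Fisher's exact test, p = 0.000398), and the X share was close to that of the other X pooled peaks (31.05%, Fisher's exact test, odds ratio 1.19, p = 0.621), so an excess near starts was not shown on X.

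Chromosome V held fewer thresholded peaks than its share of the pooled list. V had 23 of 214 peaks (10.7%) against 19.7% of the other pooled peaks (two-sided Fisher's exact test, p = 0.000696, adjusted p = 0.00244 over 7 chromosomes). The mitochondrial genome had 25 of 214 (11.7%) and no other pooled peak, which restates that all its peaks lie above the signal at which the list stops (43.6). X held 43 peaks, I 35, III 33, II 30 and IV 25, and none of these differed from the background at an adjusted p under 0.05 (0.847 for X, I, II and III, and 0.0834 for IV). Among the 214 strongest peaks of 1 replicate, IV passed both without replicate 1 (10.7% against 17.4%, Fisher's exact test, adjusted p = 0.0198) and without replicate 2 (10.3% against 16.5%, adjusted p = 0.0284). Those sets of 214 held 24 and 25 mitochondrial peaks, in that order. With mitochondrial peaks left out of the thresholded list and its background, V no longer passed (12.2% against 19.7%, Fisher's exact test, adjusted p = 0.0585). IV did not pass there either (13.2% against 17.2%, Fisher's exact test, adjusted p = 0.302).

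Ribosomal protein genes were over-represented among the genes nearest to thresholded peaks. Of the 197 genes assigned a thresholded peak, 9 (4.57%) were ribosomal protein genes, against 44 of 13404 genes assigned only other pooled peaks (two-sided Fisher's exact test, odds ratio 14.5, p = 5.97e-08, adjusted p = 9.56e-07 over 16 lists). Besides rpl-3 and rpl-35 they were rpl-11.2 (78.2), rpl-15 (71.7), rpl-23 (66.6), rpl-12 (55.1), rps-24 (52.4), rpl-6 (47.1) and rps-1 (46.8), with pooled signals in brackets. Without replicate 1 the list had 6 genes (Fisher's exact test, odds ratio 9.10, adjusted p = 0.00161). Regulators of the seam and epidermis contributed 3 of 197 genes against 21 of 13404 (Fisher's exact test, odds ratio 9.85, p = 0.00484, adjusted p = 0.0387). These were blmp-1 (61.9, summit upstream of the start), tlp-1 (61.7, upstream) and elt-1 (54.9, in an intron), which encode transcription factors. The seam and epidermal call rests on 3 genes, and it did not pass Fisher's exact test with the stronger 50% of the pooled peaks as background (adjusted p = 0.101), with the stronger 50% of the thresholded peaks (adjusted p = 0.0929) or with starts within 2000 bp only (adjusted p = 0.198). With summits inside a gene assigned to that gene, the list had 4 genes, unc-62 among them (Fisher's exact test, adjusted p = 0.00273).

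No other list passed the adjusted threshold. The cell fusion and apical junction list had 2 genes (ajm-1 at 50.9, a junction component, and vab-10 at 49.4, a spectraplakin; Fisher's exact test, p = 0.0334, adjusted p = 0.178), and the ajm-1 summit lay 48 bp from a tRNA gene. The Wnt pathway list had 1 (mig-5 at 55.4, a Dishevelled protein), the heterochronic list 1 (blmp-1) and the pan-neuronal list 1 (snt-1, synaptotagmin, at 45.4), each at an adjusted p of 0.597. The heterochronic list was tested on the 19 members found by symbol, here and in the versions below. Its miRNA genes could not be matched and so were not tested. The homeobox list had 2 (ceh-86 at 60.7 and ceh-62 at 44.9) and the neuropeptide list 3 (ins-39 at 105, ins-13 at 97.51 and nlp-40 at 52.9), also at 0.597. The ins-13 summit lay within 200 bp of the small RNA gene sls-2.2, and the nlp-40 summit lay outside protein-coding genes, 5493 bp from its start. Nuclear hormone receptors had 0 of 197 against 211 of 13404 (Fisher's exact test, p = 0.079, adjusted p = 0.316). The Hox, cuticle collagen and moulting, hedgehog-related, intestine, body-wall muscle, pharynx and germline lists had 0 genes each, at an adjusted p of 1. With summits inside a gene assigned to that gene, the Hox list had 1 gene, unc-62 (signal 46.9, in its 5' UTR). The Wnt list then had 2, mig-5 and mom-1. Neither list passed (Fisher's exact test, adjusted p = 0.319 for Hox and 0.256 for Wnt). Among the 214 strongest peaks of replicate 1 alone the heterochronic list had 5 genes (ain-1, blmp-1, lin-14, lin-28 and lin-41; Fisher's exact test, adjusted p = 7.36e-05), and among those of replicate 2 alone it had 1; the difference between replicates was not tested.

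Genes with known links to CEH-16 or to the strain had no thresholded peak. The gene ceh-16 itself (III from 8622735 to 8626314) was the nearest start to no peak in any of the lists. The fusogen gene eff-1 had a strongest pooled peak of 17.5 (rank 9050), egl-18 of 19.3 (rank 6216) and elt-6 of 18.4 (rank 7604), the latter both encoding GATA factors of the seam. The APC-related gene apr-1 had 15.1 (rank 14924) and was in neither replicate list, and unc-119, the marker gene of the strain, had 19.1 (rank 6467).

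The engrailed-type core TAATTA was not more frequent at thresholded summits than beside them. It lay within 50 bp of 8 of 213 summits (3.76%), against 7.04% in the windows 500 bp to the left and 7.04% to the right (two-sided exact McNemar test, p = 0.189 for each flank), and it was within 50 bp of 3.74% of the 214 thresholded summits and 5.26% of the other pooled summits (Fisher's exact test, p = 0.439, adjusted p = 0.494 over 9 fixed patterns). The related word TAATTG was at 10.8% of summits against 7.04% to the left (exact McNemar p = 0.229) and 4.69% to the right (p = 0.0351), and at 10.7% of thresholded against 9.17% of other pooled summits (Fisher's exact test, adjusted p = 0.494). The shorter core TAAT was less frequent at summits (47.9%) than in the left flank (62.9%, exact McNemar p = 0.00221) and the right flank (63.8%, p = 0.000987). The A and T control words were also less frequent, AATATT at 2.80% against 12.3% of other pooled summits (Fisher's exact test, p = 1.59e-06, adjusted p = 7.16e-06) and TTTAAA at 7.94% against 17.6% (adjusted p = 0.000271). GAGAGA was more frequent, at 19.2% against 6.64% (Fisher's exact test, p = 1.06e-09, adjusted p = 9.56e-09). Mean GC content within 200 bp of the summit was 39.8% ± 5.96 (SD over 189 nuclear thresholded peaks) and 34.7% ± 5.10 (SD over 29786 other nuclear pooled peaks).

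In the scan of all 6-base words, 272 were more frequent and 89 less frequent at thresholded summits (Fisher's exact test, adjusted p under 0.05 over all words). Without replicate 1 the counts were 154 and 51, and without replicate 2 they were 135 and 41. The leading word was CGCGCA, within 50 bp of 14.02% of thresholded summits and 1.67% of the others (Fisher's exact test, odds ratio 9.63, adjusted p = 3.5e-15), followed by GCGCGC at 9.81% against 0.883%. The depleted word of smallest p was AAAATT, at 21.96% against 46.05% (Fisher's exact test, adjusted p = 1.37e-10). CGCGCA also led with mitochondrial peaks left out (15.9%), but GCGCGC led for autosomal peaks, CCCTGC with the stronger 50% of peaks, AGCGTG within 25 bp and ACACAC without replicate 2, where CGCGCA was second (10.7% against 1.91%, Fisher's exact test, odds ratio 6.20).

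Summits near tRNA genes were over-represented. A tRNA gene lay within 200 bp of 21 of 214 thresholded summits (9.81%, exact 95% interval 6.18 to 14.6) and of 0.977% of the other pooled summits (two-sided Fisher's exact test, odds ratio 11.0, p = 1.18e-14). Without replicate 2 the count was 15 of 214 (Fisher's exact test, odds ratio 6.47, p = 5.94e-08). For the nuclear peaks alone the count was 12 of 189 (6.35%, Fisher's exact test, odds ratio 6.87, p = 5.66e-07). This is the comparison of like with like, since the other pooled peaks included none on the mitochondrial genome. The ce10 lists held 211 thresholded peaks, and 210 of the 214 ce11 peaks had a ce10 peak on the same chromosome with a signal within 0.1%.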

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

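Nuclear-only and autosomal-only versions and the single-start IDR fit were chosen after seeing the data. Of 271 alternative values, 224 kept their direction and side of the threshold or stayed within their range, among them all those for promoter share, replicate overlap and tRNA proximity. Gene lists supplied 130 of the 224, and several lists had no assigned gene in any setting and so little room to change. The total is therefore no measure of stability. IDR refit values moved in 3 cases and held in 2, rank correlations in 4 and 1, and word-scan counts in 9 and 7. The cause was not tested for the others below, except where the setting itself removes peaks or the fit failed. Depth is unknown, so its effect could not be examined.

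The IDR model gave 124 peaks under 0.01, 142 when ranked by the score column and 5480 from the single starting point, where the mixture had collapsed and the count has no meaning. With summits within 50 bp, 184 peaks passed, a fit that 1 of 24 starts reached. The rank correlation was 0.305 for summits within 50 bp, -0.0278 for peaks in the top 1000 of either replicate, 0.309 for thresholded peaks and 0.0389 for nuclear ones. Choosing peaks by their signal in either replicate can by itself lower such a correlation, so -0.0278 alone does not show disagreement. Pearson's r of the log2 signal was 0.52 for those 887 peaks, mitochondrial ones included. Words more and less frequent numbered 96 and 24 with the stronger 50% of peaks, and 159 and 45 within 25 bp; nuclear peaks gave 137 less frequent. With 1 replicate left out, the counts ran from 135 to 154 and from 41 to 51.

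Differences below are in percentage points, thresholded minus background. With the stronger 50% of thresholded peaks, chromosome I was at -0.800, IV at -9.70 (now past the threshold), the seam list at 1.99 (no longer past it), the fusion list at -0.148, Wnt at -0.200, pan-neuronal at -0.156 and TAATTA against other peaks at 1.28. With nuclear peaks, II was at 1.08 and V at -7.49, no longer past the threshold. The seam list lost its call at 1.299 with the stronger background and at 1.21 within 2000 bp, where the fusion list was at -0.144, heterochronic at -0.136 and pan-neuronal at -0.170. By gene body the Hox list was at 0.438. TAATTA was at -3.76 against other peaks for autosomal peaks, under 0.05 only at an unadjusted p of 0.036, and with flanks at 1000 bp it was at -6.16 against the right flank (past the threshold) but 0.0 against the left. TAAT was at -15.02, -15.96 and -18.9 (left flank, right flank, other peaks), all past the threshold.

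With either replicate left out, the homeobox list ran from -0.0197 to 0.373, the fusion list from -0.161 to 0.905 and the collagen list from -0.282 to 0.215. III ran from -0.0789 to 3.49 and X from -0.919 to 2.64. TAATTA ran from -2.82 to 0.469 against the left flank and from -1.09 to 1.31 against other peaks. The heterochronic list passed only without replicate 2, at 2.48. IV ran from -6.67 to -6.24, past the threshold both times.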

Other observations

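Small structural RNA genes lay near many thresholded peaks. A snRNA, snoRNA or rRNA gene was within 200 bp of 22 of 189 nuclear thresholded summits (11.6%) and of 0.436% of the other nuclear pooled summits (two-sided Fisher's exact test, p = 9.97e-24), a test chosen after seeing the data. Among them, 5 summits lay beside sls-2 genes, which encode the spliced leader SL2 RNA, of 18 annotated. These included sls-2.2 (pooled signal 97.51, the peak assigned to ins-13 above), sls-2.4 (95.02) and sls-2.8 (71.2). Around ceh-16 itself, within 20 kb to either side, the pooled list held 3 peaks where 13.03 would fall by length alone, and the strongest had a signal of 17.7. Replicate 1 held 4 there (8.31 by length) and replicate 2 held 5 (13.03 by length), the strongest of them at 28.9 and rank 221 in that list.

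Of the tests that follow, that on mitochondrial bins and those on words at promoter-proximal summits other than the TAATTA difference itself were chosen after their results or related ones had been seen. The test of a 12-base sequence at the X peaks was written before its own result. The X peaks themselves had drawn attention in a set singled out after the values were seen. The mitochondrial peaks were spread over the whole of that genome: 100% of its 14 bins of 1 kb held a thresholded summit, and 49.8% of its bases lay inside peaks. An excess of mitochondrial DNA over the control is a candidate explanation that needs such a spread, although 25 summits on so short a genome leave few bins empty in any case. TAATTA lay within 50 bp of 12% of mitochondrial summits, against 17.3% of mitochondrial positions (one-sided permutation p = 0.824), a value inside the range of random draws (4% to 32%), so homeodomain sites were neither shown nor excluded. No biological explanation was tested beyond this.

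A hypothesis for the X peaks is that they include recruitment sites of the dosage compensation complex, whose recruitment elements carry a 12-base consensus, TCGCGCAGGGAG. This sequence, with at most 2 mismatches, lay within 100 bp of 30.2% of the 43 X thresholded summits (exact 95% interval 17.2 to 46.1), against 0.368% of other X pooled summits (Fisher's exact test, p = 2.53e-20) and 2.05% of autosomal thresholded summits (p = 2.95e-07). With 3 mismatches allowed the contrast was smaller, at 37.2% of X and 17.8% of autosomal thresholded summits, against 3.33% and 3.95% of the other pooled summits on each, so looser matches were frequent at autosomal thresholded summits too. The consensus was exact at the strongest nuclear peak (X from 11094123 to 11094134) and in an intron of Y41G9A.17 (X from 2997121 to 2997132), and read TCGCGCAGGGAC upstream of xol-1 (X from 8036399 to 8036410). Matches with 1 mismatch also lay at the peaks near nspc-17, in the mom-1 intron and in pks-1, and a match with 2 near ins-39. Of the 15 X peaks among the 25 strongest nuclear peaks, 10 (66.7%) had at most 2 mismatches. The scan words CGCGCA and CCCTGC (on the other strand) lie inside the consensus, so this test partly repeats the scan on the same peaks. TAATTA at the X summits differed from the flanks by 0.0 percentage points (bootstrap 95% interval -9.30 to 9.30), which leaves homeodomain sites open. Whether CEH-16 binds there or the signal may come from such sites in any immunoprecipitate could not be told from these lists, and 30 of the 43 peaks lacked the sequence.

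For the promoter-proximal peaks, GC content was weighed as a technical explanation. Matching each nuclear thresholded peak to 20 pooled peaks of the same GC lowered the difference in promoter share from 20.1 to 14.6 percentage points (bootstrap 95% interval 7.25 to 21.9). The interval excluded 0, so GC content alone did not account for the difference, but it did not clear the bound set in advance for excluding a large part. TAATTA was at 0 of 111 promoter-proximal summits, -4.50 percentage points from the mean of the flanks (permutation p = 0.0383 over the 3 windows of each summit). With no summit holding the word, resampling could not pass 0, so the bound set in advance decides nothing. By flank the shares were 6.31% (left, exact McNemar p = 0.0156) and 2.70% (right, p = 0.25). The control word AATATT was lower at these summits too (0.901% against 10.8% and 9.01%), TTTAAA was at 8.11% against 14.4% (exact McNemar p = 0.21) and 10.8% (p = 0.629), and TAATTG was at 5.41% against 5.41% and 3.60%. TAATTA at 0 of 111 summits (exact 95% interval 0 to 3.27%) argues against this word, within 50 bp, as the source of most of these peaks. Other homeodomain sites at these summits, such as TAATTG, were neither shown nor excluded.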
